A study of Homo sapiens with 6 samples.

How the data were processed

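RNA of HepG2 cells was hybridised to 6 Affymetrix arrays as biotin-labelled cRNA, per the labels' protocols. The cells had been transfected with 30 nM of a scrambled siRNA or of a UHMK1-specific siRNA and were collected 24 h later. The titles give 3 arrays to each group and number them 1 to 3. No label says whether the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

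The deposited table holds log2 expression values with 2 decimals for 135750 probe sets. They were made with Transcriptome Analysis Console 4.0 and RMA, per the submitters' processing notes. RMA corrects the background, normalizes arrays by quantiles and summarises the probes of a probe set. The deposited values are not identical in distribution between arrays: the median over all probe sets was 4.40, 4.43 and 4.42 on the scrambled siRNA arrays and 4.43, 4.55 and 4.41 on the UHMK1 siRNA arrays, and the highest value was 19.93 on every array but UHMK1 siRNA array 2, where it was 19.36. On those other arrays 12 or 13 probe sets stood at 19.93, which may be a ceiling of the scale, and 0 did on UHMK1 siRNA array 2. The values were used as deposited, with no further normalization. The mean correlation with the other arrays of the group ranged from 0.990 for UHMK1 siRNA array 2 to 0.994 for the scrambled siRNA arrays, across probe sets, which are not independent. No array repeated the values of another. RMA can compress large changes, and whether the deposited scale compresses or stretches changes was not tested. Fold sizes are therefore those of the deposited scale. A quantile step holds the overall level of each array fixed, so a change of total RNA per cell cannot be read from these values.

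Probe sets were named through the array's gene table, with symbols updated by Entrez gene ID to the RefSeq gene table of assembly GRCh38.p14. The table gave 1 symbol to 36176 probe sets and several to 1119, and did not list 98455. Only probe sets with 1 symbol were named. For the 1576 genes with several such probe sets, the one with the highest mean over all 6 arrays was used, a choice blind to group. This left 33616 genes, of which 24321 matched the RefSeq table by Entrez gene ID and 17338 are protein-coding. The others keep the symbol of the gene table. Among genes of the lists below, COL1A1, SF1, ASAP1, BIRC3, FDXR, HNRNPK, HSP90B1 and SLC10A1 are represented by a probe set without an Entrez gene ID. The build of the probe sets is not given in the sources used here, so no coordinates are printed.

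UHMK1 siRNA was compared with scrambled siRNA in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, two-sided, all 6 arrays, no covariates). Adjusted p-values are Benjamini-Hochberg values over the 33616 genes unless a list is named, and a gene rose or fell where its adjusted p was under 0.05. Changes are log2 differences, UHMK1 siRNA minus scrambled siRNA, with the moderated standard error. Fixed before the data were examined were this design, the first group of other settings below, 19 gene lists with 405 entries (375 of them measured) and the rule for the genes named. The lists cover G2/M and G1/S genes, YAP/TAZ, p53 and NF-kB target genes, hepatocyte secretory genes, hepatocyte metabolic and regulator genes, interferon response, splicing factor, UHMK1 partner, stress response and UPR, cholesterol synthesis, nucleotide synthesis, replication-dependent histone, and hypoxia and glycolysis genes, and markers of immune, endothelial, fibroblast and stellate, and biliary cells. They were written from general knowledge. The rule takes UHMK1, the 12 largest rises and 12 largest falls among genes past the threshold whose arrays do not overlap between groups (leaving out symbols of uncharacterised and small RNA genes), the 4 members of each list with the smallest p, and every measured UHMK1 partner gene. Genes outside the rule are said to be named after their values were seen.

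Lists were tested against all other genes with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists. Of the calls camera made, 0 held when the correlation between genes was estimated for each list, and that adjusted p is given beside each. The median of a list was also compared with 10000 random lists matched on mean expression in 40 bins (a permutation p). This draws genes and not arrays, so it takes the members of a list as independent. The estimated correlation within lists ranged from -0.10 (fibroblast and stellate) to 0.46 (hepatocyte secretory). Where it is above 0, this p is too small. The test was tried on simulated data: means and residual spreads of the 33616 genes were used to simulate UHMK1 siRNA against scrambled siRNA, with 50 genes changed at each of 4 fold sizes. It recovered 6% of the 1.5-fold, 36% of the 2-fold, 88% of the 4-fold and 86% of the 8-fold changes, and 7 of 115 calls were false. Many more genes passed in the data (1141), which loosens the adjusted threshold there. The simulation also took each gene's estimated spread as its true one. The shares recovered are therefore not the power of the test on these data.

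The first group of other settings comprised quantile normalization, median centring, the replicate number as a block, a variance trend with robust fitting (statmod 1.5.0), array weights, the mean of a gene's probe sets, a filter on dim genes, all probe sets, other thresholds, fry (which tests a list against no change), and leaving out each array in turn. Chosen after seeing the data were cyclic loess normalization, quantile normalization with UHMK1 siRNA array 2 left out, the matched random lists, and probe sets with an Entrez gene ID only. Also chosen after the values were seen were 32 families of protein-coding genes defined by their symbols and 2 lists of genes of the ERK pathway, which appear under the other observations. Figures were drawn with matplotlib 3.10.9.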

Results

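Gene expression was measured in HepG2 cells, a human liver cancer cell line that keeps many traits of hepatocytes, 24 h after transfection with 30 nM siRNA. A scrambled siRNA had been given to the cells behind 3 arrays and an siRNA against UHMK1 to the cells behind the other 3. UHMK1 encodes a protein kinase with a U2AF homology motif, known for phosphorylating the splicing factor SF1. The comparison asks which transcripts of a liver cancer cell differ between the UHMK1 siRNA and the scrambled siRNA. It cannot separate the loss of UHMK1 from other effects of the siRNA. It covered 33616 named genes, of which 17338 are protein-coding, and the number of arrays limits its precision.

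UHMK1 itself had the largest fall of any tested gene. Its log2 level was 11.47 ± 0.25 (SD, n = 3) after scrambled siRNA and 8.03 ± 0.29 (SD, n = 3) after UHMK1 siRNA. The change of -3.43 (SE 0.20, 95% confidence interval -3.88 to -2.98) had limma's adjusted p = 0.000113. On the deposited scale it was 10.8-fold and left 9.26% of the signal. On the single arrays UHMK1 stood at 11.42, 11.24 and 11.74 after scrambled siRNA and at 8.36, 7.80 and 7.94 after UHMK1 siRNA, so the groups did not overlap. UHMK1 was read by 1 probe set.

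GINS2 and CDC6 of DNA replication and thymidylate synthase (TYMS) were among the transcripts that fell after UHMK1 siRNA. So were the chemokines CCL20 and CXCL8, the hexokinase HK2 and the glucose transporter SLC2A1. The cyclin CCNG2 and the fibrinogen chain FGG were among those that rose. Of the tested genes, 244 rose and 897 fell at an adjusted p under 0.05 in limma, so that 78.6% of the 1141 changed genes were lower. Among protein-coding genes 199 rose and 803 fell. Falls were also larger than rises: 477 genes fell and 106 rose at least 2-fold, while 42 genes fell and 0 rose at least 4-fold. No gene at an unadjusted p under 0.05 was 4-fold higher either, the largest log2 change upward being 1.80. The median size of a changed gene was 2.00-fold, the smallest was 1.52-fold, and the median residual SD of a gene was 0.222 on the log2 scale. At an unadjusted p under 0.05 there were 5132 genes, where chance gives 1681.

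UHMK1 siRNA array 2 stood apart from the other arrays. Over the 8865 genes with a mean log2 level above 8, its median lay at -0.25 from the scrambled siRNA mean, against -0.03 and -0.06 for UHMK1 siRNA arrays 1 and 3. Without that array 237 genes rose and 662 fell, and 73.6% of the changed genes were lower. Cyclic loess normalization, chosen after seeing the data because it removes trends with brightness, gave 406 higher and 739 lower genes, 64.5% of them lower, and 970 of these were among the 1141. Fewer genes passed with 5 arrays: 77 rose and 365 fell without scrambled siRNA array 1, 70 and 319 without scrambled siRNA array 2, and 95 and 375 without scrambled siRNA array 3. The counts were 105 and 567 without UHMK1 siRNA array 1, and 125 and 553 without UHMK1 siRNA array 3.

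The largest falls after UHMK1 siRNA covered several kinds of protein. CD164, a sialomucin of the cell surface and endosomes, fell by 3.27 on the log2 scale (SE 0.16, adjusted p = 9.41e-05), from 14.29 ± 0.13 to 11.02 ± 0.16 (SD, n = 3). The immediate early gene IER3 fell by 3.07 and CCL20, a chemokine, fell by 3.05, from 14.71 ± 0.19 to 11.66 ± 0.15. UXS1, which makes UDP-xylose, fell by 3.01, and C1D, a cofactor of the nuclear exosome, fell by 2.92. HK2, the hexokinase typical of tumours, fell by 2.84, from 9.74 ± 0.18 to 6.91 ± 0.12. The change was -2.75 for PRPF4, a component of the U4/U6 small nuclear ribonucleoprotein, and -2.75 for SPRY4, a feedback inhibitor of receptor tyrosine kinase signalling. CEMIP, which takes part in hyaluronan breakdown, fell by 2.63 and DHX33, a DEAH-box helicase, fell by 2.59. C1DP1, a pseudogene copy of C1D, fell by 2.69. Probes for near-identical copies can bind either transcript, so the falls of C1D and C1DP1 are not separate observations.

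**Figure D1:**
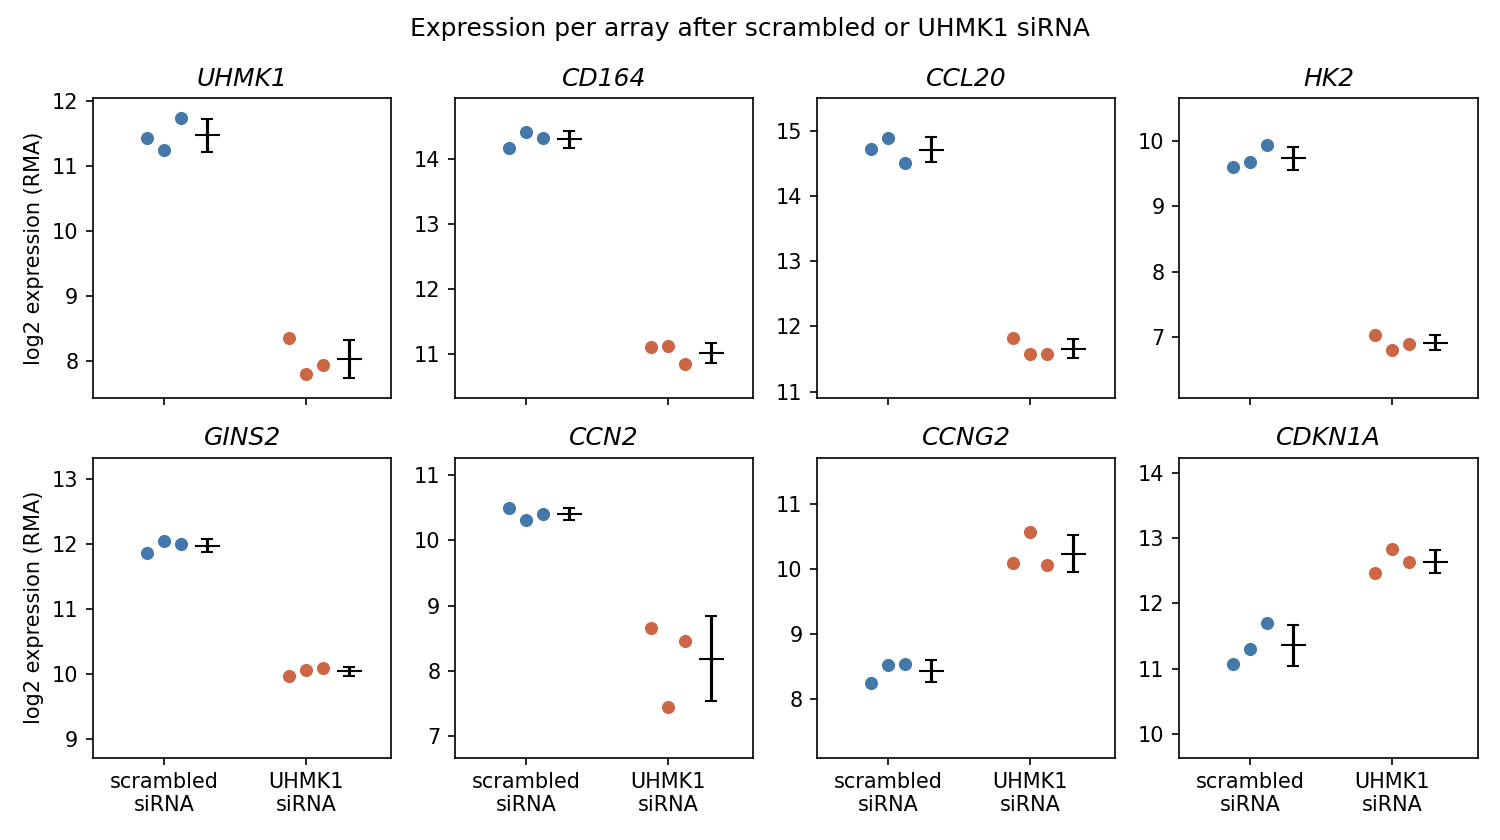
Log2 expression (RMA) of 8 genes on each of the 6 arrays, blue for scrambled siRNA and orange for UHMK1 siRNA, with a bar at the group mean and whiskers of 1 SD (n = 3); each panel has its own vertical range. UHMK1, CD164, CCL20, HK2, GINS2 and CCN2 were lower on every UHMK1 siRNA array than on every scrambled siRNA array, and CCNG2 and CDKN1A were higher on every one.

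The largest rise was that of CCNG2, an unconventional cyclin linked to cell cycle arrest, at 1.80 on the log2 scale (SE 0.18, adjusted p = 0.00173), from 8.43 ± 0.16 to 10.23 ± 0.29 (SD, n = 3). The endocytic adaptor DAB2 rose by 1.75 (SE 0.17, adjusted p = 0.00147) and the glycine transporter SLC6A9 rose by 1.75 (SE 0.15, adjusted p = 0.000798). ODAM and the mitochondrial transporter SFXN3 each rose by 1.57, and PIK3R3, a regulatory subunit of phosphoinositide 3-kinase, rose by 1.55. Among genes of liver metabolism, PLA2G12B rose by 1.51, the medium-chain acyl-CoA synthetase ACSM3 went from 9.87 to 11.37 and the glutathione transferase GSTA2 from 8.08 to 9.58. MXRA8 rose by 1.48 and TNRC6B, a partner of Argonaute proteins in microRNA silencing, rose by 1.46. FAM3C2P, a pseudogene copy of FAM3C, rose by 1.53. FAM3C, named after its values were seen, rose by 1.26 (adjusted p = 0.00892), and probes can bind both copies, as they can for GSTA2 and its close relatives. UHMK1 and the other 23 genes with the largest rises and falls kept their call with any 1 array left out.

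**Figure D2:**
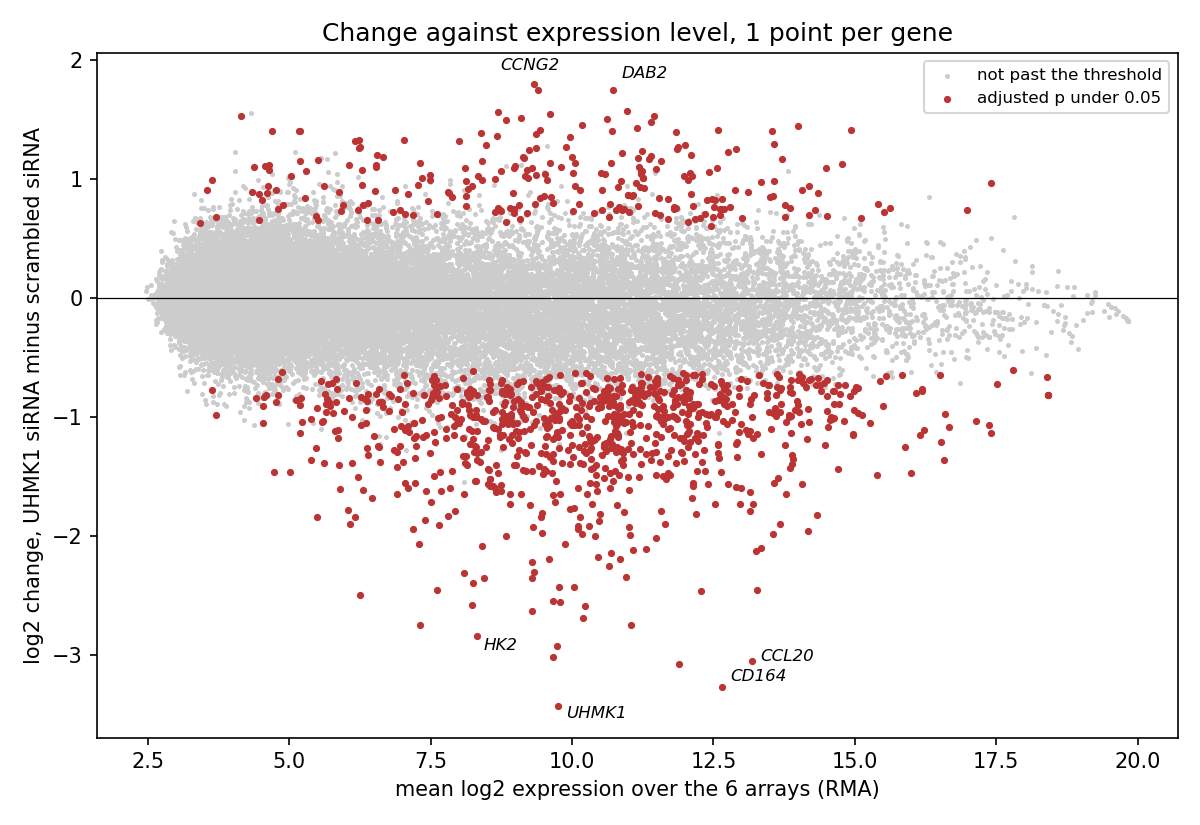
Log2 change (UHMK1 siRNA minus scrambled siRNA) of each tested gene against its mean log2 expression over the 6 arrays; red points passed an adjusted p under 0.05 in limma and grey points did not. The 897 red points below 0 reach -3.43 at UHMK1, and the 244 above 0 reach 1.80 at CCNG2.

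Genes of the G1/S transition and of DNA replication were lower after UHMK1 siRNA in large number. Of 37 measured, 21 fell and 0 rose, all 37 changes were negative, and the median was -0.78. GINS2, a subunit of the replicative helicase complex, fell by 1.92 (SE 0.14, adjusted p = 0.000377), from 11.97 ± 0.10 to 10.05 ± 0.07 (SD, n = 3). CDC6, which loads the helicase, fell by 1.39, UHRF1 fell by 1.47 and thymidylate synthase, TYMS, fell by 1.44. Adjusted over the list alone, 33 fell. The list was lower than the other genes in camera (adjusted p = 8.24e-29), with an adjusted p = 0.163 with an estimated correlation. The number of falls was 19 without UHMK1 siRNA array 2, 10 without scrambled siRNA array 2 and 11 without scrambled siRNA array 3.

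Of the 40 genes of G2 and mitosis, 4 fell and 0 rose, 39 changes were negative, and the median was -0.36. The number of falls is near the share among all tested genes of such brightness. At a mean log2 level of 10 to 12, 271 of 2769 genes fell, and at 12 to 14, 158 of 1669. Random lists matched on mean expression had a median of -0.10 on average. MAD2L1, of the spindle checkpoint, fell by 1.56 (SE 0.17, adjusted p = 0.00185), the cyclin CCNA2 fell by 1.05, the anaphase activator CDC20 fell by 1.14, and the cyclin CCNB1 fell by 0.70. In the list taken alone, 16 fell. Camera gave an adjusted p = 3.91e-10 for a lower list, and an adjusted p = 0.252 with an estimated correlation. There were 4 falls without UHMK1 siRNA array 2, 1 without scrambled siRNA array 2 and 2 without scrambled siRNA array 3. CCNB1 lost its call with any array left out, at changes between -0.80 and -0.59, while CCNA2 lost it without scrambled siRNA array 2 (-0.97) and CDC20 without scrambled siRNA arrays 2 (-1.11) or 3 (-1.06). The 14 measured replication-dependent histone genes had 0 calls in limma, with 4 lower and 0 higher at an unadjusted p under 0.05, and 3 lower when adjusted over the list alone. Their median was -0.25 (camera adjusted p = 0.0526, adjusted p = 0.634 with an estimated correlation), and -0.10 without UHMK1 siRNA array 2. H2BC14 stood at -0.78 (adjusted p = 0.0572), H2BC12 at -0.64, H1-5 at -0.63 and H2BC4 at -0.39. The list passed in camera without scrambled siRNA array 1 (adjusted p = 0.0310) and without UHMK1 siRNA array 3 (adjusted p = 0.0136).

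Of 18 measured genes of purine and pyrimidine synthesis, 7 fell and 0 rose, 17 changes were negative, and the median was -0.63. The purine enzyme ATIC fell by 1.01, the phosphoribosyl pyrophosphate synthetases PRPS2 and PRPS1 fell by 1.00 and 0.95, and PFAS, also of purine synthesis, fell by 0.81. Among the pyrimidine enzymes of this list only DHODH, named after its values were seen, passed (-0.71), while TYMS, in the G1/S list, fell by 1.44. DHODH lost its call with any array left out, and CTPS1, also named after its values were seen, passed without UHMK1 siRNA array 1 (-1.37). Adjusted over the list alone, 13 fell. Camera gave an adjusted p = 3.38e-11, and an adjusted p = 0.163 with an estimated correlation. Without UHMK1 siRNA array 2 there were 4 falls, without UHMK1 siRNA array 3 there were 3, and without scrambled siRNA array 1, 2 or 3 there was 1. PFAS lost its call without any array but UHMK1 siRNA array 2 (-0.86 to -0.75), PRPS1 without any scrambled siRNA array (-1.03 to -0.91), ATIC without scrambled siRNA arrays 1 (-0.98) or 3 (-0.99), and PRPS2 without scrambled siRNA array 2 (-0.94).

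Of 18 NF-kB target genes, CCL20 and CXCL8, both chemokines, fell, and 0 rose. CXCL8 fell by 1.42 (SE 0.16, adjusted p = 0.00230), whereas ICAM1 stood at -0.53 (adjusted p = 0.152) and NFKB1 at -0.43 (adjusted p = 0.167). With adjustment over these genes only, 2 fell. The list's median was -0.19 (-0.26 to -0.07 with 1 array left out), with camera's adjusted p = 0.0402 and an adjusted p = 0.252 with an estimated correlation. The call was lost under quantile normalization (adjusted p = 0.0634), under cyclic loess normalization (0.0776), without scrambled siRNA arrays 2 (0.0642) or 3 (0.0842), and without UHMK1 siRNA arrays 1 (0.0575) or 3 (0.110). Among 16 hypoxia and glycolysis genes, HK2, the glucose transporter SLC2A1 and the pyruvate dehydrogenase kinase PDK1 fell, and 0 rose. SLC2A1 fell by 1.83, from 15.25 ± 0.09 to 13.42 ± 0.42 (SD, n = 3), PDK1 fell by 0.84, and LDHA stood at -0.37 (adjusted p = 0.233). The same 3 passed when adjusted over the list alone, and the median was -0.24 (camera adjusted p = 0.00506, adjusted p = 0.252 with an estimated correlation). Without UHMK1 siRNA array 2 the median was -0.10. There were 2 falls without UHMK1 siRNA array 2. PDK1 lost its call without any array but UHMK1 siRNA array 1, at changes between -0.94 and -0.75.

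Genes targeted by YAP and TAZ, the transcriptional effectors of the Hippo pathway, included falls of CCN2 and ANKRD1 and no rise among 19 measured. CCN2, a matricellular protein, fell by 2.22 (SE 0.29, adjusted p = 0.00417), with levels of 8.66, 7.44 and 8.45 on UHMK1 siRNA arrays 1, 2 and 3. ANKRD1 fell by 1.80 (SE 0.20, adjusted p = 0.00218). CCN1 stood at -0.96 (adjusted p = 0.113) and NT5E at 0.68 (adjusted p = 0.0900). Adjusted over the list alone, 2 rose and 3 fell. The list's median was -0.07 (camera adjusted p = 0.747, adjusted p = 0.798 with an estimated correlation), and it was 0.01 after cyclic loess normalization.

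Of 23 p53 target genes, 2 rose and 2 fell. The cell cycle inhibitor CDKN1A rose by 1.29 (SE 0.19, adjusted p = 0.00884), from 11.36 ± 0.32 to 12.64 ± 0.18 (SD, n = 3), and the cyclin CCNG1 rose by 1.13. GDF15, a secreted stress factor, fell by 1.18 and the exonuclease AEN fell by 0.80. Within the list by itself, 2 rose and 4 fell. The median was -0.12 (camera adjusted p = 0.747, adjusted p = 0.826 with an estimated correlation), it was 0.01 after cyclic loess normalization and 0.05 without UHMK1 siRNA array 2. AEN lost its call with any array left out (-0.88 to -0.73), and CDKN1A lost it without scrambled siRNA array 2 (1.26).

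Among hepatocyte genes few changes passed. After scrambled siRNA some secretory genes lay near the top of the scale, such as APOA2 at 19.57. Some metabolic genes lay near its lower end, such as TAT at 3.94, and the filter on dim genes kept 15 of 23. Both genes were named after their values were seen. Changes near either end may be missed, which was not tested, so genes that did not pass are not shown to be unchanged. Of 27 secretory genes 1 rose and 0 fell: the fibrinogen chain FGG rose by 0.97 (SE 0.14, adjusted p = 0.00728), from 16.92 ± 0.08 to 17.89 ± 0.07 (SD, n = 3). The fibrinogen chain FGB stood at 0.70 (adjusted p = 0.0668), ITIH1 at 0.76 (adjusted p = 0.103) and APOC3 at 0.63 (adjusted p = 0.118). When adjusted over the list alone, 4 rose. The median was 0.09 (0.06 to 0.20 with 1 array left out), with camera's adjusted p = 0.00925 and an adjusted p = 0.634 with an estimated correlation. That call was also lost without scrambled siRNA array 1 (adjusted p = 0.0510) and without UHMK1 siRNA arrays 1 (0.0925) or 3 (0.0697), while FGB joined FGG among the rises without UHMK1 siRNA array 2. KNG1, named after its values were seen, fell by 0.92 without UHMK1 siRNA array 1. Of 23 metabolic and regulator genes, FABP1, the liver fatty acid-binding protein, rose by 0.76, while NR0B2, a repressor of bile acid synthesis, fell by 1.27 and the transcription factor CEBPA fell by 0.91. CYP8B1 stood at 0.43 (adjusted p = 0.254). The same counts, 1 rise and 2 falls, held when adjusted over the list alone, and the median was 0.09 (camera adjusted p = 0.373, adjusted p = 0.634 with an estimated correlation). FABP1 lost its call without any array but UHMK1 siRNA array 2 (0.69 to 0.81), NR0B2 without scrambled siRNA arrays 2 (-1.10) or 3 (-1.30), and CEBPA without scrambled siRNA arrays 2 (-0.88) or 3 (-0.85) or UHMK1 siRNA arrays 1 (-0.83) or 3 (-0.89).

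Of 19 measured cholesterol synthesis genes, mevalonate kinase, MVK, rose by 0.77 and SREBF2, the transcription factor that drives the pathway, rose by 0.79. In all, 17 changes were positive and the median was 0.29. The squalene epoxidase SQLE stood at 0.59 (adjusted p = 0.0565) and HSD17B7 at 0.71 (adjusted p = 0.0592). Adjusted over the list alone, 9 rose and 1 fell. Camera gave an adjusted p = 1.83e-06 for a higher list, and an adjusted p = 0.252 with an estimated correlation. After cyclic loess normalization 7 rose. MVK lost its call with any array left out (0.65 to 0.84), as did SREBF2 (0.64 to 0.94), so that 0 genes of the list passed without UHMK1 siRNA array 1 or 3 or any scrambled siRNA array. Without UHMK1 siRNA array 2, SC5D, named after its values were seen, rose by 0.73.

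**Figure D3:**
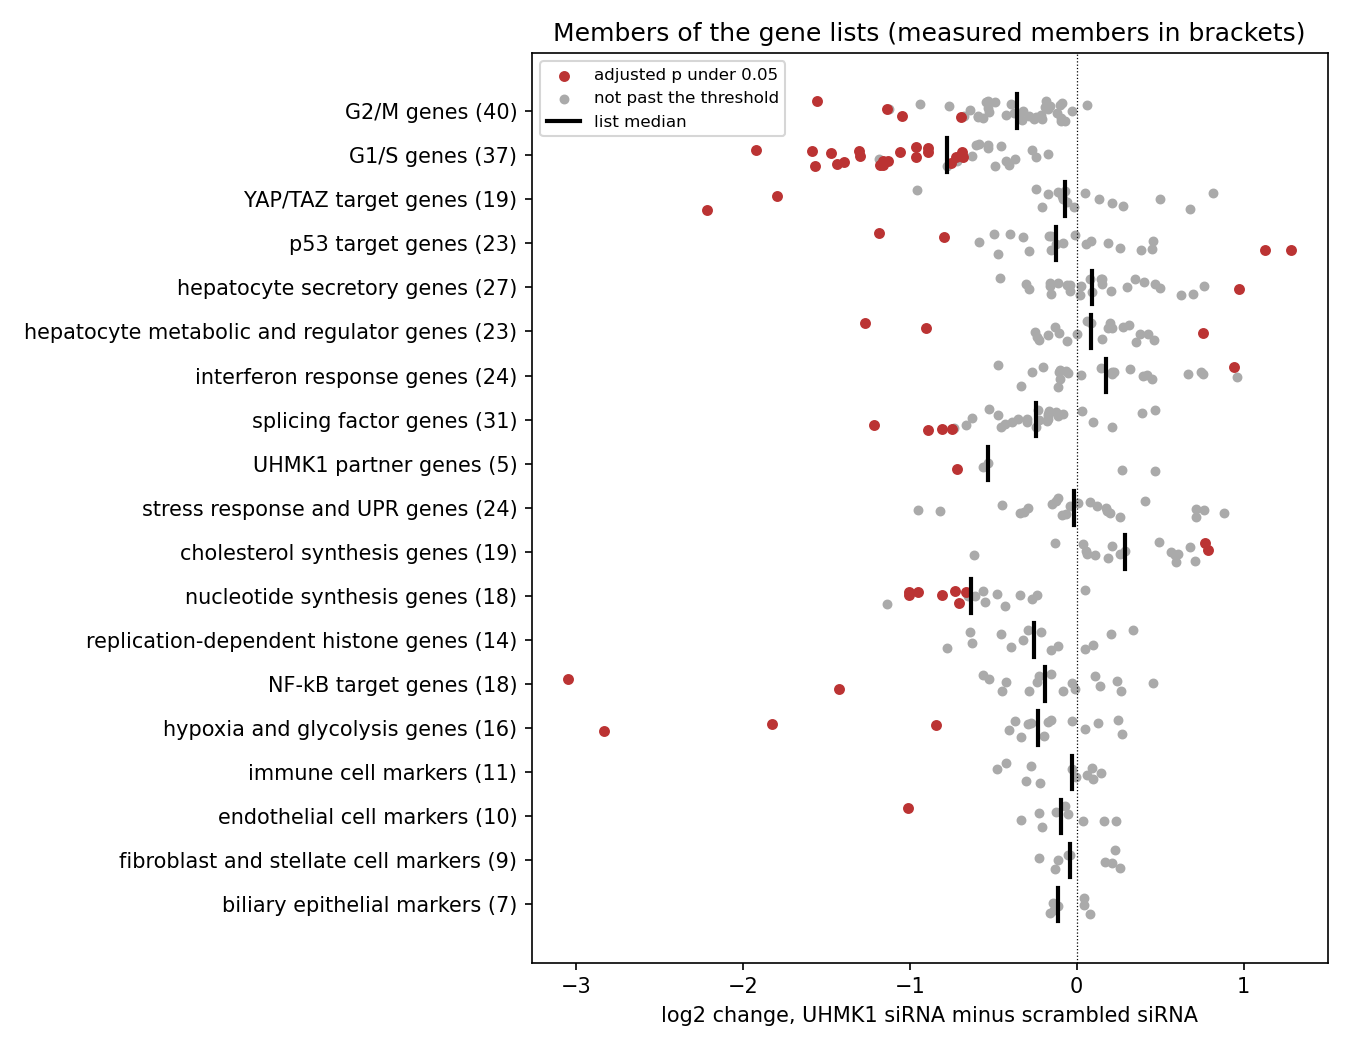
Log2 change (UHMK1 siRNA minus scrambled siRNA) of each measured member of the 19 gene lists, red where the gene passed an adjusted p under 0.05 over all genes and grey where it did not, with a black bar at the list's median. The medians of the G1/S list and the nucleotide synthesis list lie at -0.78 and -0.63, and that of the cholesterol synthesis list at 0.29.

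Splicing factors, which include a substrate of the UHMK1 kinase, had 4 falls and 0 rises among 31 measured. HNRNPC, which packages nascent transcripts, fell by 1.21 (SE 0.14, adjusted p = 0.00275), the SR proteins SRSF7 and SRSF10 fell by 0.89 and 0.81, and SF3B4, of the U2 complex, fell by 0.75. In the list taken alone, 8 fell. The median was -0.25 (camera adjusted p = 2.99e-05, adjusted p = 0.449 with an estimated correlation), and -0.14 without UHMK1 siRNA array 2. Only 2 falls passed without UHMK1 siRNA array 1, 2 or 3, and 1 passed without scrambled siRNA array 1, 2 or 3. SRSF10 lost its call with any array left out (-0.87 to -0.70), SF3B4 without any array but UHMK1 siRNA array 3 (-0.77 to -0.68), and SRSF7 without any scrambled siRNA array or UHMK1 siRNA array 3 (-0.94 to -0.84).

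Of 5 measured genes whose products are known substrates or partners of UHMK1, or are reported beside it, 1 fell and 0 rose. CDKN1B, the cell cycle inhibitor p27, fell by 0.72 (SE 0.14, adjusted p = 0.0292), from 10.54 ± 0.07 to 9.82 ± 0.10 (SD, n = 3), and lost its call with any array left out (-0.78 to -0.68). PIMREG, also in the G2 and mitosis list, stood at -0.56 (adjusted p = 0.0778), MYBL2, also in the G1/S list, at -0.53 (adjusted p = 0.115), SF1, also in the splicing list, at 0.47 (adjusted p = 0.468) and PAM at 0.27 (adjusted p = 0.540). SF1 was read by a probe set without an Entrez gene ID, and with a linked one it stood at 0.11 (adjusted p = 0.829). With adjustment over these genes only, 3 fell, and the median was -0.53 (camera adjusted p = 0.191, adjusted p = 0.425 with an estimated correlation).

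The interferon list had 1 rise and 0 falls among 24 genes: RIGI, a sensor of viral RNA, rose by 0.94 (SE 0.18, adjusted p = 0.0271). IFIT1 stood at 0.96 (adjusted p = 0.0758), IFIT3 at 0.76 (adjusted p = 0.0772) and IFIH1 at 0.75 (adjusted p = 0.128). Adjusted over the list alone, 5 rose. The median was 0.18 (0.08 to 0.22 with 1 array left out), with camera's adjusted p = 0.0130 and an adjusted p = 0.252 with an estimated correlation, and the call was lost without scrambled siRNA array 1 (adjusted p = 0.0536). RIGI lost its call without any array but UHMK1 siRNA array 3 (0.84 to 1.04), while IFIT1 and IFIT3 passed without UHMK1 siRNA array 2 (1.19 and 0.92). The stress response and unfolded protein list had 0 calls among 24 genes in limma, with 5 higher and 3 lower at an unadjusted p under 0.05. Within the list by itself, 2 rose and 1 fell. ASNS, which makes asparagine, stood at 0.88 (adjusted p = 0.0503), PHGDH at 0.71 (adjusted p = 0.0581), SLC7A11 at 0.72 (adjusted p = 0.141) and SDF2L1 at -0.82 (adjusted p = 0.0528). ASNS, PHGDH and SLC7A11 passed without UHMK1 siRNA array 2 (1.08, 0.86 and 0.95), and after cyclic loess normalization. SDF2L1 passed after cyclic loess normalization and, at -0.98, without UHMK1 siRNA array 1. HSP90B1, named after its values were seen, also passed without UHMK1 siRNA array 1 (-1.38). It was read by a probe set without an Entrez gene ID, at 7.94 after scrambled siRNA. The list's median was -0.02 and its mean 0.03, camera placed it on the higher side (adjusted p = 0.444, adjusted p = 0.802 with an estimated correlation), and the median was 0.07 after cyclic loess normalization.

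Among markers of other cell types, 1 passed. Of 11 immune cell markers, 0 passed in limma, with 1 lower and 0 higher at an unadjusted p under 0.05 and 0 adjusted over the list alone. LYZ stood at -0.48 (adjusted p = 0.157), CD68 at -0.31, CSF1R at -0.42 and CD3E at -0.22. The median of the immune list was -0.03 (camera adjusted p = 0.444, adjusted p = 0.634 with an estimated correlation), and -0.21 to -0.04 with 1 array left out. After scrambled siRNA, LYZ had a mean log2 level of 18.62 and CD3E one of 5.97. Among 10 endothelial markers the junction protein ESAM fell by 1.01 (SE 0.15, adjusted p = 0.00713) and 0 rose, the same when adjusted over the list alone. TIE1 stood at -0.34, CLEC4M at 0.23 and VWF at -0.22, and the median was -0.10 (camera adjusted p = 0.373, adjusted p = 0.680 with an estimated correlation). Of 9 fibroblast and stellate cell markers and 7 biliary markers, 0 passed in limma, 0 when adjusted over the list alone, and 0 at an unadjusted p under 0.05. ACTA2 stood at -0.23, COL1A1 at 0.26, PDGFRA at 0.17 and RGS5 at 0.23, and the fibroblast list had a median of -0.04, a mean of 0.03 and a camera direction upward (adjusted p = 0.636, adjusted p = 0.703 with an estimated correlation). Among the biliary markers KRT19 stood at -0.14, SOX9 at -0.14, SPP1 at -0.16 and KRT7 at 0.08, and the median was -0.11 (camera adjusted p = 0.903, adjusted p = 0.906 with an estimated correlation).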

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

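Of the tests in this part, those on the excess of falls (except the splits), on silencing and on pseudogenes were chosen after the result was seen, and the slopes between array pairs after the other slope. Groups of 3 arrays are too small for an outlier test, and with 1 contrast no effects could be set against each other.

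Probe sets without a single gene name lie outside the tested genes and hold a signal as well. Fitted with all 135750 probe sets in limma, 13 of these 99574 were higher and 26 lower after UHMK1 siRNA at an adjusted p under 0.05. Of these, 7 carry several gene symbols, 5 of them lower, and 32 are not listed in the gene table.

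More genes fell than rose after UHMK1 siRNA, 897 against 244, and genes with a mean log2 level above 8 had a median change of -0.11. After cyclic loess normalization, which removes trends with brightness, 64.5% of the changed genes were still lower. Without UHMK1 siRNA array 2, 73.6% were lower. Neither step alone removed the excess of falls. They were not applied together, and the shares that would count against either source were set after the result was seen. A technical cause of the excess is therefore not excluded. The share was lower in both tests than the 78.6% over all 6 arrays. A response to the loss of UHMK1, or of any other transcript the siRNA silences, stays open as well. The 6 arrays allow 10 splits into groups of 3, too few for a share under 0.05; the real split called 1141 genes and the highest of the others called 0 in limma, with 871 to 1517 genes at an unadjusted p under 0.05 against 5132. The G1/S list median moved by 0.78 in the real split and by at most 0.39 in the others. Every other split mixes the treatments on both sides, so any real effect partly cancels and partly adds to the spread. Fewer calls and a smaller median then follow from the design, so the splits cannot weigh chance.

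Besides UHMK1, 41 genes fell at least 4-fold and 0 rose as much, among them CD164, which fell by 3.27 on the log2 scale where UHMK1 fell by 3.43. Pseudogenes that share sequence with a changed gene do not account for this as a class, since 92.7% of the 41 are protein-coding, although C1D and C1DP1 are such a pair. Direct silencing of other transcripts by the siRNA was not tested, and the count of 41 does not decide it. It cannot be told apart from a response to the loss of UHMK1, because the siRNA sequence and the 3' UTR sequences were not used here and the UHMK1 siRNA group is treated as 1 reagent. An independent siRNA or a rescue with UHMK1 would separate them.

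UHMK1 siRNA array 2 read lower among bright genes than UHMK1 siRNA arrays 1 and 3. A technical offset of that array is a possible source, as bright genes with no sign of a response would then read lower too. The 2303 such genes (p above 0.5 without it) did, at a median of -0.18 from the scrambled siRNA mean (bootstrap 95% interval -0.20 to -0.17). A difference of that sample's cells or RNA would read the same way, so this does not tell them apart. A stronger response in that sample stays open: its changes had a slope of 0.968 (0.941 to 0.993) on the mean changes of UHMK1 siRNA arrays 1 and 3 over the 899 genes called without it, but error in that mean and the choice of genes by it both lower such a slope. Each UHMK1 siRNA array was also set against the scrambled siRNA array of the same number, which shares no array between pairs. The slope was here the covariance of pair 2 with the pair that picked the genes, divided by that of the remaining pair with it. It was 1.09 (1.04 to 1.14) against pair 3 over 486 bright genes picked on pair 1. Against pair 1, over 464 picked on pair 3, it was 1.02 (0.974 to 1.07). All intervals here resample genes, which share the same arrays, and the slopes do not settle the source.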

How the results depend on the processing

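Cyclic loess normalization, quantile normalization without UHMK1 siRNA array 2, matched random lists and probe sets with an Entrez gene ID only were chosen after seeing the data. UHMK1 stayed lower and past the threshold under every setting, between -3.60 and -3.30 with an array left out. Of the 57 called genes named besides UHMK1, 0 changed direction, 22 lost their call under some setting with all probe sets, another model or another normalization, and 20 with an array left out. Where no construction is named, the cause of a change was not tested.

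The counts of higher and lower genes were 123 and 514 at an unadjusted p under 0.05 with a 2-fold change, and 67 and 337 at an adjusted p under 0.01. They were 433 and 1377 after the filter on dim genes, which tests fewer genes, and 52 and 244 over all probe sets, which tests more. Higher genes numbered 400 with trend and robust fitting, 402 with array weights (UHMK1 siRNA array 2 had a weight of 0.397) and 406 after cyclic loess normalization. With 1 array left out, which leaves 5 arrays, 70 to 237 genes were higher and 319 to 662 lower. Deviations of same-numbered arrays correlated at 0.05, 0.03 and -0.04 across genes, which gives no sign that the replicate numbers pair the samples. A shared culture or day is not excluded, since no label says what the numbers mark. With the replicate block, which takes up degrees of freedom, 146 genes were higher and 576 lower.

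With an estimated correlation in camera the calls of 9 lists were lost at unchanged medians: G2/M -0.36, G1/S -0.78, hepatocyte secretory 0.09, interferon 0.18, splicing -0.25, cholesterol synthesis 0.29, nucleotide synthesis -0.63, NF-kB -0.19, and hypoxia and glycolysis -0.24. Fry asks another question, whether a list differs from no change and not from the other genes, so it neither keeps nor ends camera's calls: the hepatocyte secretory (0.09) and interferon (0.18) lists did not pass in it, and the UHMK1 partner (-0.53) and immune (-0.03) lists did. Relative to matched random lists, the hepatocyte secretory (0.18), splicing (-0.15), NF-kB (-0.14) and hypoxia and glycolysis (-0.16) calls were lost. The remaining calls are not thereby shown to hold, since that comparison takes the genes of a list as independent. The NF-kB call was also lost under quantile (-0.21) and cyclic loess normalization (-0.12), the dim filter (-0.23) and Entrez-linked probe sets (-0.15). The histone list passed with trend and robust fitting and with the mean of probe sets (-0.25 both).

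Lists whose medians changed sign did not pass under those settings. For the stress and UPR list they were 0.0292 with array weights, 0.0433 with the mean of probe sets, 0.0655 after cyclic loess, 0.046 after quantile normalization without UHMK1 siRNA array 2, 0.0067 with Entrez-linked probe sets, and 0.0565 relative to matched random lists. They were 0.0109 for YAP/TAZ, 0.0054 for p53 and 6e-04 for immune markers after cyclic loess, 0.031 for p53 after quantile normalization without UHMK1 siRNA array 2, -0.06 for hepatocyte metabolic genes after the dim filter, and 0.17 and 0.0569 for the fibroblast list with the mean of probe sets and after quantile normalization without that array. KRT7 stood at -0.0028 after quantile normalization. The main median of the stress and UPR list, -0.0167, lay 0.0565 above the average median of matched random lists, which is no change of sign.

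With an array left out, list medians ranged from -0.2917 to -0.0983 (hypoxia and glycolysis), -0.345 to -0.14 (splicing), 0.0033 to 0.1283 (hepatocyte metabolic), -0.2067 to -0.04 (immune), 0.055 to 0.20 (hepatocyte secretory), 0.0767 to 0.22 (interferon), -0.26 to -0.0717 (NF-kB), -0.35 to -0.10 (histones), -0.14 to 0.05 (p53), -0.065 to 0.0683 (stress and UPR), -0.0633 to 0.10 (fibroblast), -0.19 to 0.0542 (endothelial) and -0.0683 to 0.0117 (biliary), and SOX9 from -0.3183 to 0.0567. Values near the lower end of the scale, where signal is close to background, limit the detection of changes in dim genes: 6 of the 1141 changed genes had a mean log2 level under 4.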

Other observations

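All families and genes in this part, the list of 10 ERK activity genes and the test of ERK-induced genes were chosen after the main results were seen; the values of the ERK-induced genes themselves had not been examined. Of 16 nucleolar UTP and NOP genes, 7 fell and 0 rose, with a median of -0.72. NOP14 fell by 1.05, UTP4 fell by 0.89, UTP23 fell by 0.87, NOP16 fell by 0.79 and UTP20 fell by 0.75. Among 30 RNA polymerase subunits 5 fell and 0 rose, with a median of -0.39: POLR3K (-1.22), POLR1D (-1.07), POLR1B (-0.96), POLR1G (-0.95) and POLR1C (-0.91). Of 75 mitochondrial ribosomal protein genes 7 fell, led by MRPS27 (-2.25), MRPL36 (-2.17), MRPS12 (-1.84) and MRPS7 (-1.73), and the median was -0.29. For comparison, 803 of all 17338 protein-coding genes fell, as did 271 of the 2769 genes with a mean log2 level of 10 to 12. Of 54 cytosolic ribosomal protein genes 0 passed in limma, with 1 higher and 4 lower at an unadjusted p under 0.05, and the median was -0.10 (camera adjusted p = 0.415, adjusted p = 0.897 with an estimated correlation). Camera's adjusted p was 3.59e-10, 8.50e-08 and 3.59e-10 for the nucleolar, polymerase and mitochondrial families, and 0.252, 0.252 and 0.283 with an estimated correlation. With 1 array left out, 0 to 4 of the nucleolar falls and 1 to 5 of the polymerase falls passed, and 5 or 6 of the mitochondrial ones.

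Of 8 metallothioneins 4 fell and 0 rose, with a median of -0.88: MT1G (-1.14), MT1X (-1.12), MT2A (-1.09) and MT1H (-0.90), whose sequences are alike enough for probes to bind several (camera adjusted p = 1.56e-06, adjusted p = 0.252 with an estimated correlation). Without scrambled siRNA array 2, 0 of them passed, and 1 passed without scrambled siRNA array 1 or 3 or UHMK1 siRNA array 1. Of 31 serpins, 4 made by hepatocytes rose, SERPINA6 (1.17), SERPINA4 (1.15), SERPINA5 (0.86) and SERPINC1 (0.77), while SERPINB9 fell by 0.89. With 1 array left out, 1 or 2 of the rises and 0 falls passed, and the median of 0.02 was -0.04 under quantile normalization. In all, camera placed 16 of the 32 families lower and 1 higher, and 0 passed with an estimated correlation. Other rises were those of MTTP (1.41), which loads lipid onto lipoproteins, CIDEB (1.41) and the stress gene NUPR1 (1.43). Other falls were those of CDK2 (-2.43), E2F5 (-2.43), CDCA5 (-2.36) and the clamp loader subunit RFC5 (-2.01).

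As a hypothesis, output of the ERK MAP kinase pathway may be lower after UHMK1 siRNA. Of 10 genes that report ERK activity, 6 fell and 0 rose, with a median of -1.23: SPRY4 (-2.75), DUSP6 (-2.19), EPHA2 (-1.65), CCND1 (-1.43), ETV5 (-1.27) and ETV4 (-1.18). Camera's adjusted p over the ERK lists was 2.69e-11, and the p with an estimated correlation was 0.00554, but this list was chosen after falls among its members had been seen. Of 20 ERK-induced genes whose values had not been examined, 2 of them also in the first list, 2 fell, DUSP5 (-0.87) and ELK3 (-1.40), 0 rose, and the median was -0.27, short of the -0.30 and the 4 falls set as needed (camera adjusted p = 7.84e-05, p = 0.0824 with an estimated correlation). Without the shared genes, a choice made after the values were seen, the median of the other 18 was -0.28 (camera p = 9.08e-05, p = 0.0617 with an estimated correlation). The filter on dim genes, which leaves 11 of the 20, gave 5 falls and a median of -0.56, quantile normalization 3 and -0.32, trend and robust fitting 4 and -0.27, and Entrez-linked probe sets 5 and -0.27. With 1 array left out, 1 or 2 falls passed and the median lay between -0.33 and -0.21. The hypothesis stays open, and phosphorylated ERK was not measured.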
